A study of Arabidopsis thaliana with 18 samples.

How the data were processed

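Transcript levels were measured on Affymetrix ATH1 arrays in whole Arabidopsis seedlings of background Col-0 carrying DUO1 in pMDC7, after 12 days in constant light. RNA was labelled with biotin in 1 cycle, per the labels. The deposited values are intensity values, MAS5 signals on a linear scale, made in GCOS per the submitters' processing notes. The versions of MAS5 and GCOS and the scaling target are not given in the sources used here. The trimmed mean of every array, without the lowest and highest 2% of probe sets, was 100 in the values, so each array had been scaled to it. Of 22810 probe sets, 64 controls were left out and 22746 were tested, with no filter on signal.

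Arrays were grouped by the labels into induced and not induced plants at 6 h, 12 h and 24 h, 6 groups of 3. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples. No group had the inducer without the DUO1 construct, so effects of DUO1 and of the treatment itself were not separated. Probe sets took gene names only from the annotation and RefSeq tables provided. Of those tested, 13513 (59.4%) had 1 gene, 503 had several and 8730 had none, and 152 of the 13350 genes had more than 1 probe set.

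Log2 signals were fitted with limma 3.58.1 (R 4.3.3, statmod 1.5.0), with 1 mean per group over all 18 arrays, empirical Bayes moderation with an intensity trend, and 12 residual and 7.69 prior degrees of freedom. Induced and not induced plants were compared at each time and over all times by an F test. Differences in response between times, and changes with time without induction, were further contrasts. P-values were adjusted by Benjamini and Hochberg within each contrast, with a threshold of 0.05. The values were read and the array measures computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Correlations of responses used R, and figures matplotlib 3.10.9.

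The background level of an array was the highest signal among its 27 control probe sets for transcripts not spiked in, 3.3 to 10.1 over the arrays (median 5.66), a definition chosen after the data were seen. Where a group lay at or below it on all 3 arrays, the fold change is a lower bound, taken from the other group and the background level. On simulated data with 200 changed probe sets, 48.0%, 48.0% and 58.0% of 2-fold and 73.0%, 68.0% and 71.0% of 4-fold changes were recovered in the comparisons set up as 6 h, 12 h and 24 h. For bright probe sets the recovery of 2-fold changes was 91.5%, 84.8% and 86.0%. It was highest for 6 h, although the real 6 h groups had the largest spread (median SD 0.163 and 0.155, later groups 0.123 to 0.141). These shares therefore do not measure how recovery differed between the real times. Among unchanged probe sets 5, 3 and 6 were called.

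Genes were named by a rule written before the data were examined. At each time it took the 12 largest rises and 6 largest falls among probe sets with 1 gene, an adjusted p under 0.05, a change of at least 2-fold and separated groups. It added all measured sperm cell genes and DUO1 targets named by the study, and up to 4 genes past the threshold of every other list. For each other contrast it took the 5 largest rises and 5 largest falls, and GI. PYK10, COR47, AUR3, AtVEX1, ANX2 and further response regulator genes, the genes named as changed at all 3 times, gene families, root genes and probe sets without a gene were named after their values were seen.

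The 20 lists covered sperm cell genes, DUO1 targets named by the study, pollen vegetative cell and tube, egg, central cell and synergid, tapetum and anther, miR159-targeted GAMYB-like, G2 to M phase, DNA replication, photosynthesis, salicylic acid and defence, jasmonate, abscisic acid and drought, heat shock, chemical detoxification, touch and wound, circadian clock, auxin, cytokinin, root and stable reference genes. Of their 287 entries 51 matched a probe set named with a single gene in the annotation used here, and only these are called measured throughout. For the GAMYB-like and heat shock lists 0 did. Entries without a match may be covered by the 8730 probe sets without a gene name, so their absence from the array is not shown. Lists of at least 5 measured genes were tested with camera (preset correlation 0.01), with camera with an estimated correlation, and with fry.

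The alternatives fixed before the data were examined were quantile normalization, 1 median for all arrays, a filter on mean signal (40th percentile), an offset of 4.82 before the log, no intensity trend, array weights, the replicate number as a block, no probe sets of several genes, only the arrays compared, and leaving out each array. Raising signals to background, the hybridisation controls as a covariate and tests of gene families were added after the data were seen. Arrays were also regrouped in all other splits of 3 and 3 (10 splits for 6 arrays, 100 for 12, and 100 drawn with seed 1 for 18).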

Results

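The samples were whole seedlings of Arabidopsis thaliana, accession Col-0, that carried DUO1 in pMDC7, an oestradiol-inducible expression vector. DUO1 is a MYB transcription factor of the male germline, so its expression in seedlings is ectopic. Plants were grown for 12 days in constant light, and RNA was taken at 6 h, 12 h and 24 h with or without induction of DUO1. Each of the 6 groups held 3 ATH1 arrays, 18 in all. The median signal of an array lay between 34.3 and 39.5, and 72.3% to 83.6% of its probe sets lay above the background level of that array. Signals are given as mean ± SD over 3 arrays, whose number limits the precision. For a gene at background on all 3 arrays of a group, the change is given as a lower bound ("at least N-fold"), and for a gene at background on 2 of 3 arrays as signals only. None of the 22746 probe sets tested was named DUO1 in the annotation used here, so its own transcript was not analysed here.

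The first comparison asked which seedling genes responded 6 h after induction of DUO1. MGH3, the sperm cell histone H3 and a known target of DUO1, reached a signal of 178 ± 29.9 (SD, n = 3) in induced plants, at least 27.6-fold above plants without induction (limma, adjusted p = 2.78e-06). TET11, a tetraspanin gene, reached 49.7 ± 17.7 against 3.21 ± 4.74 without induction, where 2 of 3 arrays were at background (adjusted p = 0.0026). AT4G26010, a peroxidase gene, fell from 105 ± 18.3 to 23.0 ± 5.03 (log2 change -2.2 ± 0.24 SE, adjusted p = 2.93e-05). The expansin genes EXPA7 and EXPA18, which are expressed in root hairs, fell by 1.52 and 0.87 on the log2 scale (adjusted p = 0.0316 and 0.0477).

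Among the other genes that rose at 6 h, the nitrate transporter gene NRT2.5 reached 24.4 ± 9.47 (at least 3.64-fold), the protease gene SBT4.13 reached 22.6 ± 3.85 (at least 3.51-fold) and AT1G15190 reached 21.8 ± 4.27 (at least 3.37-fold). AT4G20790 rose at least 1.80-fold, AT1G73050 at least 1.48-fold, and AT5G08480 rose from 3.59 ± 3.03 to 27.1 ± 4.89. AT3G54310, AT3G12000, AT4G09410 and AT2G04600 passed the test with mean induced signals of only 4.87, 3.84, 3.55 and 4.36. Their log2 changes were -0.01, -0.07, -0.11 and -0.05 once signals below background were raised to it. Among the falls, the pectin methylesterase inhibitor gene AT4G25250 went from 25.5 ± 8.26 to 3.82 ± 2.72 (adjusted p = 0.00914). The peroxidase gene AT1G34510 fell at least 2.04-fold and AT5G22555 at least 1.17-fold. AT1G33770 and AT1G24390 fell from signals of 5.90 ± 3.06 and 4.71 ± 3.10, which were at background on 2 of 3 arrays, and lost their calls when signals were raised to background.

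Of the gene lists fixed beforehand, the sperm cell list had 2 measured members at 6 h, of which MGH3 rose and TET12 stood at 3.10 ± 3.18 against 10.2 ± 5.43 (adjusted p = 0.283). Adjusted over the list alone, 2 passed, TET12 as a fall with 2 of 3 induced arrays at background. TET11 was the 1 measured gene of the list of DUO1 targets named by the study. It rose, and it was 1 of 1 adjusted over the list alone, which for 1 gene is the unadjusted p. That list was chosen on these samples and is not independent evidence. Of 3 root genes, EXPA7 and EXPA18 fell, 2 also adjusted over the list alone, and the root beta-glucosidase gene PYK10 had a log2 change of -0.02 (adjusted p = 0.971). Of the other lists with a measured gene, 0 members passed limma over all probe sets. Adjusted over the list alone, 2 chemical detoxification genes and 1 touch and wound gene passed.

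In total, 220 probe sets changed at 6 h by limma, 130 up and 90 down, of which 63 rises and 42 falls were at least 2-fold. With each array shifted to 1 median, the split was 89 up and 133 down. All 220 separated the 3 induced from the 3 other arrays, which is no independent support, since they were called on these same arrays. Of all tested probe sets 14.7% did so, where chance gives 10%. The count was 124 without induced replicate 2 and 98 without induced replicate 3, and it was 67 when only the 6 h arrays were fitted, where TET11 had an adjusted p of 0.0515. EXPA7 and EXPA18 each lost their 6 h call in 10 alternatives, with adjusted p up to 0.125 and 0.198.

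**Figure D1:**
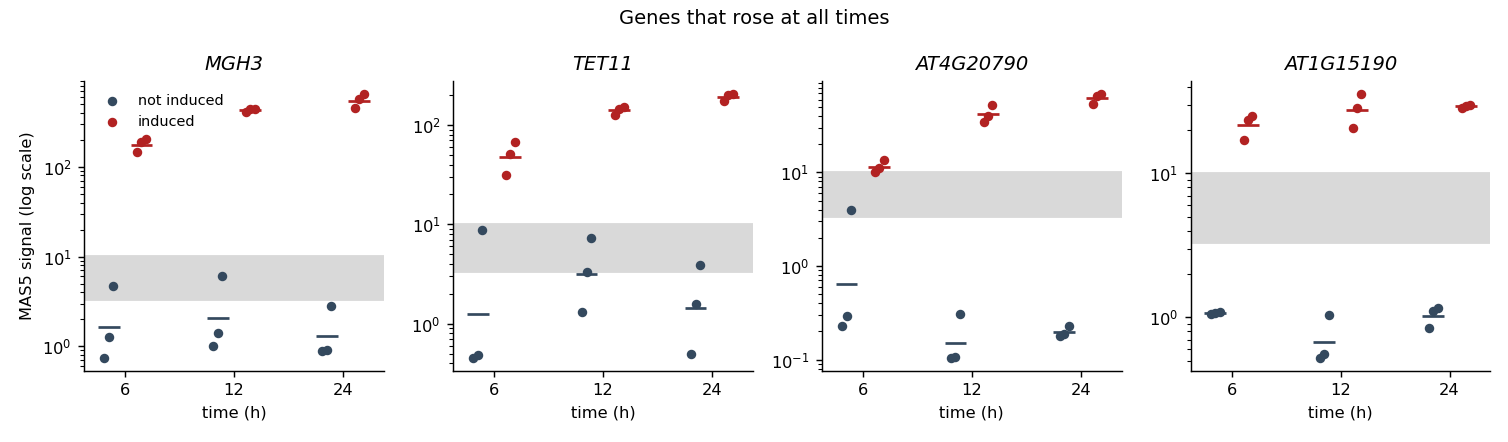
MAS5 signal on a log axis for MGH3, TET11, AT4G20790 and AT1G15190 against time in hours, with 1 point per array and bars at the mean of the log signals for each group. The grey band spans the background levels of the 18 arrays, 3.3 to 10.1, and in each panel the induced arrays lie above the arrays without induction at 6 h, 12 h and 24 h.

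At 12 h, AT4G20790 reached 42.4 ± 8.85 in induced plants, at least 7.46-fold above plants without induction (adjusted p = 1.94e-06). MGH3 stood at 427 ± 17.0 against 2.83 ± 2.79 (adjusted p = 7.77e-08) and TET11 at 141 ± 14.1 against 3.95 ± 2.99 (adjusted p = 0.000454), each with 2 of 3 arrays without induction at background. AT4G21020 reached 91.4 ± 4.70, at least 16.3-fold above plants without induction. The sugar transporter gene AT5G26250 rose from 2.91 ± 3.20 to 53.6 ± 12.7, and AT5G37450 rose from 5.27 ± 4.65 to 95.6 ± 15.2 (adjusted p = 0.00183 and 3.52e-05). The peroxidase gene AT3G49960 fell at least 4.24-fold, from 24.3 ± 7.55 (adjusted p = 0.00688).

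Further genes that rose at 12 h were AT1G15190 and AT2G37070, at least 4.92-fold and 4.96-fold, AT3G60780 at least 3.92-fold, and the calmodulin-like gene CML37 at least 3.09-fold. AT4G18180 and AT5G65100 rose at least 2.68-fold and 2.27-fold. AT3G28550 and AT4G30320 fell from 20.5 ± 7.25 and 12.8 ± 2.72 to 2.60 and 2.48, at background on 2 of 3 induced arrays. AT1G13540 and AT4G03880 passed with signals without induction of only 5.09 and 3.87, at background on 1 and 2 of 3 arrays, and AT4G09410 with all 6 arrays at background, so its change was not measured. All 3 lost their calls when signals were raised to background. AT4G30320 lost its call in 6 alternatives, and AT3G49960 had an adjusted p of 0.051 without induced replicate 2.

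In the gene lists at 12 h, MGH3 was again the sperm cell gene that rose, and TET12 did not pass (adjusted p = 0.281). Adjusted over the list alone, 2 of 2 passed, but TET12 as a fall at background on all 3 arrays of both groups, so its change was not measured. TET11 rose, also adjusted over the list alone, in the list that is not independent evidence. Of 3 Aurora kinase genes, which act at the G2 to M phase, AUR2 rose by 0.74 and AUR1 by 0.42 on the log2 scale (adjusted p = 0.00118 and 0.041), with 2 past the test adjusted over the list alone. AUR3 had a log2 change of 0.51 (adjusted p = 0.306). Of 10 pollen vegetative cell and tube genes, the actin gene ACT11 rose by 0.50 (adjusted p = 0.0167), 1 also adjusted over the list alone. EXPA7 and EXPA18 fell by 1.51 and 1.18 (adjusted p = 0.00983 and 0.00133), and PYK10 had a log2 change of -0.12 (adjusted p = 0.684). The glutathione transferase gene GSTU25 fell by 0.74 (adjusted p = 0.000305), 1 of 3 detoxification genes under both adjustments. In the remaining lists 0 members passed limma over all probe sets. Adjusted over the list alone, 3 auxin response genes, 2 abscisic acid and drought genes and the clock gene GI did. For GI, the 1 measured clock gene, that was the unadjusted p, and limma over all probe sets gave an adjusted p of 0.11.

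Altogether 1102 probe sets changed at 12 h, 662 up and 440 down, of which 235 rises and 185 falls were at least 2-fold, and 1091 separated the groups. With each array shifted to 1 median, the split was 492 up and 620 down. The count was 615 without induced replicate 2 and 704 without replicate 3 of the plants without induction. The call of AUR1 was lost in 9 alternatives and that of ACT11 in 3, among them the fits without replicate 2 of either group. EXPA7 lost its call without induced replicate 2 and when only the 12 h arrays were fitted, with an adjusted p up to 0.0752.

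**Figure D2:**
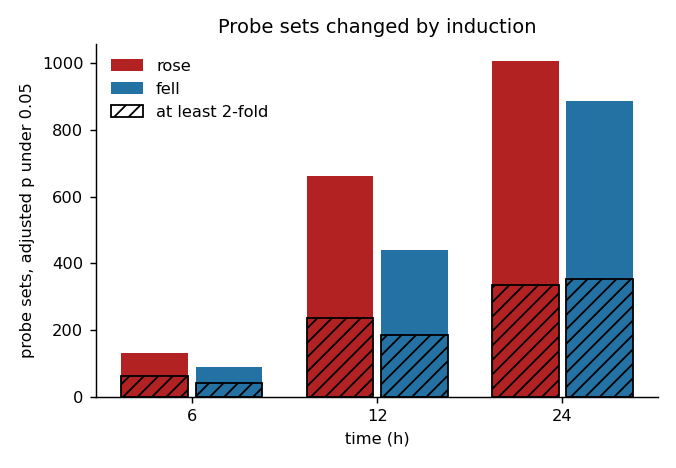
Number of probe sets that rose or fell after induction at 6 h, 12 h and 24 h at an adjusted p under 0.05, with the part that changed at least 2-fold hatched. The bars reach 130 rises and 90 falls at 6 h, 662 and 440 at 12 h, and 1007 and 887 at 24 h; with each array shifted to 1 median, falls outnumber rises at each time.

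At 24 h, MGH3 reached 551 ± 98.5 in induced plants, at least 124-fold above plants without induction (adjusted p = 1.09e-08), and TET11 reached 193 ± 14.9, at least 44.0-fold (adjusted p = 1.53e-05). AT1G71470 rose at least 19.3-fold, to 85.6 ± 16.5, AT4G20790 at least 14.2-fold, to 62.6 ± 7.93, and AT1G73510 at least 12.9-fold, to 57.4 ± 14.0. COR15A, a cold- and dehydration-responsive gene, stood at 2013 ± 259 against 542 ± 133 without induction (log2 change 1.91 ± 0.32 SE, adjusted p = 0.000476). ACT11 stood at 180 ± 24.9 against 81.7 ± 5.91 (log2 change 1.14 ± 0.12 SE, adjusted p = 2.59e-06). EXPA18 fell from 58.3 ± 7.24 to 19.4 ± 4.12 and EXPA7 from 42.7 ± 7.80 to 10.5 ± 0.55 (adjusted p = 3.18e-05 and 0.000507).

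AT4G21020 rose at least 12.6-fold at 24 h, AT3G51690 at least 8.97-fold, AT3G60780 at least 7.62-fold, AT1G15190 at least 6.69-fold and AT4G18180 at least 5.72-fold. AT1G04645 rose at least 4.33-fold and the tetraspanin gene TET16 at least 3.35-fold. AT1G54890 fell at least 5.50-fold, the receptor-like kinase gene AT1G51850 at least 4.88-fold, AT5G58784 at least 3.3-fold and TBL21 at least 2.80-fold. AT2G19970 fell from 92.7 ± 2.25 to 7.75 ± 6.04, and AT3G49960 from 35.8 ± 3.35 to 4.81 ± 7.57. Among probe sets with no gene named in the annotation used here, 252440_at reached 857 ± 98.0, at least 195-fold, and 251252_at reached 507 ± 146, at least 113-fold. The probe sets 258765_at and 253502_at fell at least 4.65-fold and 4.28-fold.

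Among the gene lists at 24 h, stress and cytokinin genes also passed the test. Of 3 abscisic acid and drought genes, COR15A and LEA4-5 rose, the latter by 2.08 (adjusted p = 0.0234), 2 also adjusted over the list alone, while COR47 had a log2 change of -0.13 (adjusted p = 0.787). Both measured genes of the cytokinin list fell, the response regulator genes RR16 from 34.4 ± 2.69 to 16.2 ± 4.18 (adjusted p = 0.00977) and ARR15 at least 2.28-fold (adjusted p = 0.0326), 2 of 2 adjusted over the list alone. Outside the list, the response regulator genes RR18, RR19, RR22 and RR23 did not pass. AUR2 rose by 0.67 (adjusted p = 0.00179), the 1 Aurora kinase gene past either adjustment, and GSTU25 fell by 0.91 (adjusted p = 1.75e-05), the 1 detoxification gene past either. ACT11 was the 1 pollen vegetative cell and tube gene past either adjustment. Among sperm cell genes MGH3 rose, 1 also adjusted over the list alone, and TET12 stood at 5.66 ± 5.13 against 7.55 ± 0.90 (adjusted p = 0.532). TET11, 1 of 1 under both adjustments, is again not independent evidence. PYK10 had a log2 change of -0.27 (adjusted p = 0.208), and adjusted over the list alone all 3 root genes passed. In the remaining lists 0 members passed limma over all probe sets. Adjusted over the list alone, 2 auxin response genes, 1 jasmonate gene and 1 egg cell gene did.

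In total, 1894 probe sets changed at 24 h, 1007 up and 887 down, of which 336 rises and 353 falls were at least 2-fold, and 1856 separated the groups. With each array shifted to 1 median, the split was 795 up and 1163 down. The count was 1161 without induced replicate 3, 1230 without induced replicate 2 and 1210 without replicate 3 of the plants without induction, and 2974 with limma's array weights. LEA4-5 and ARR15 each lost their call in 7 alternatives, and RR16 in 2, among them the fit without induced replicate 3.

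**Figure D3:**
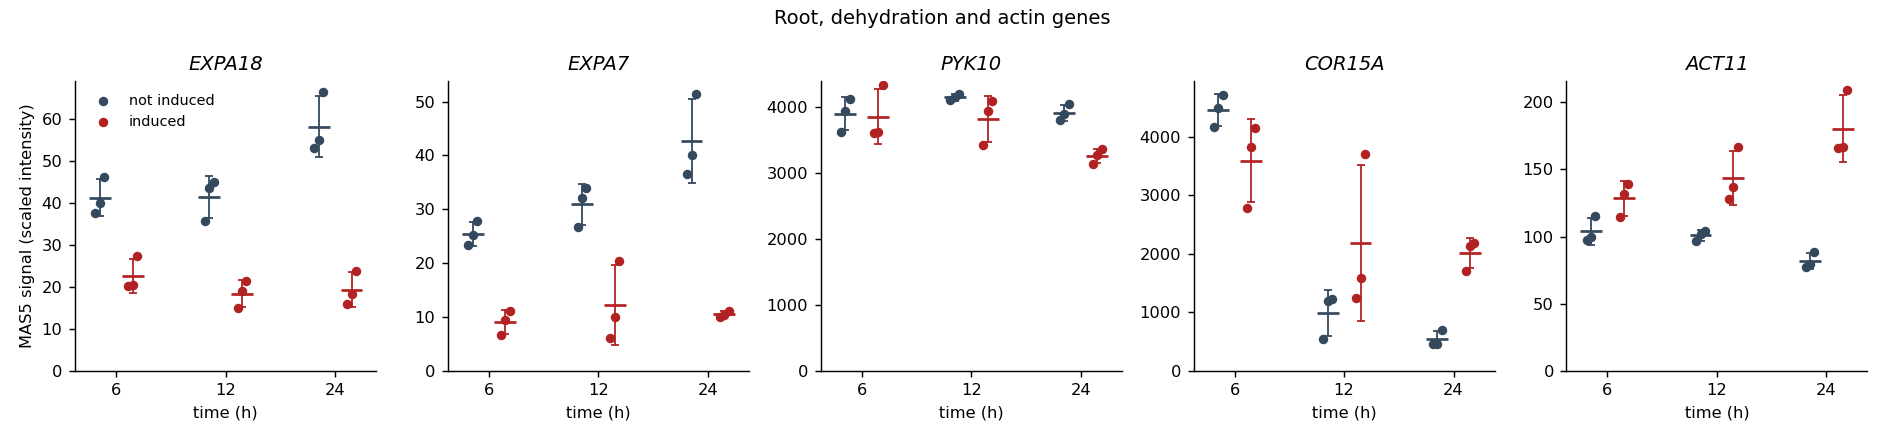
MAS5 signal of EXPA18, EXPA7, PYK10, COR15A and ACT11 against time in hours, with 1 point per array, bars at the group mean and error bars of 1 SD over 3 arrays. EXPA18 and EXPA7 were lower in induced plants at each time, while COR15A stood at 2013 ± 259 against 542 ± 133 and ACT11 at 180 ± 24.9 against 81.7 ± 5.91 at 24 h.

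Of the 20 lists, 2 had enough measured members for a test of the whole list, the 10 pollen vegetative cell and tube genes and 5 stable reference genes. By camera, 0 of the 2 lists passed at 6 h, 12 h or 24 h. The pollen list had an adjusted p of 0.263 at 24 h, or an adjusted p of 0.283 with an estimated correlation, and unadjusted camera p of 0.693, 0.533 and 0.132 at the 3 times, so 0 lists were under 0.05. The fry test, which asks whether the genes of a list moved on balance 1 way, gave the pollen list an adjusted p of 0.00364 at 24 h, and 1.29e-08 for change in either direction. ACT11 was the pollen gene that changed, and the other 9 had an adjusted p of at least 0.457, ANX2 with all arrays at background. The 5 reference genes had 0 changes by limma at each time, and median log2 changes of -0.03, 0.09 and -0.04.

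Across the 3 times, MGH3, TET11, AT4G20790, AT1G15190, NRT2.5 and SBT4.13 rose at each time, as did 75 probe sets in all. Falls at each time were found for 49 probe sets, among them AT4G26010, which fell by 2.2, 2.94 and 3.36 on the log2 scale, AT4G25250, which fell from 25.5, 17.8 and 35.2 to 3.82, 3.59 and 7.36, with 2, 2 and 1 of 3 induced arrays at background, and EXPA7, EXPA18 and EXPA9. Of the 662 rises at 12 h, 417 were also called at 24 h, against 29.3 for independent lists, and 97.1% had the same sign. Of the 440 falls, 292 were shared, against 17.2. Between 6 h and 12 h, 79 rises and 51 falls were shared, against 3.78 and 1.74, and between 6 h and 24 h 81 and 56, against 5.76 and 3.51. Different arrays were used at each time, so no control array was shared. The tests did share 1 estimate of spread per probe set, which can by itself raise the overlap above that of independent lists. Across genes, which are not independent replicates, the log2 changes of 12 h and 24 h correlated with Pearson's r of 0.360 (Spearman's rho 0.322). The r was 0.175 between 6 h and 12 h and 0.183 between 6 h and 24 h (rho 0.146 and 0.134). Over the 11373 brighter probe sets, r was 0.733, 0.400 and 0.358. A test over all times called 2377 probe sets.

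Whether responses differed between times was tested directly. The effect of induction on AT4G33550 was more positive at 12 h than at 6 h by 1.82 ± 0.22 SE on the log2 scale, that of AT2G37870 by 2.19 ± 0.31 and that of AT3G53980 by 1.62 ± 0.22 (adjusted p = 0.00137, 0.00382 and 0.00242). These 3 genes belong to the lipid transfer protein family. The effect on the peroxidase gene AT5G64120 was more negative at 12 h, with a log2 change of -2.31 against -0.82 at 6 h, which did not pass (adjusted p = 0.0728, adjusted p of the difference 0.0474). AT1G71470 stood at 4.75 induced against 2.79 not induced at 6 h, with 4 of 6 arrays at background, and rose at least 19.3-fold by 24 h (adjusted p of the difference 0.00525). Between 6 h and 12 h, 44 probe sets differed (34 up, 10 down), and between 6 h and 24 h 367 (199 up, 168 down). Between 12 h and 24 h limma called 0, with 1591 at an unadjusted p under 0.05, 12 with array weights, 18 without induced 24 h replicate 1, and 3 and 1 without 12 h replicate 3 and 24 h replicate 2 of the plants without induction. Of the genes named here, AT4G33550 and AT1G71470 kept their call in every alternative that held their probe set, while AT5G64120 lost it in 13. The clock gene GI did not pass for any pair of times (adjusted p = 0.399, 0.92 and 0.582).

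The counts of differing responses moved with single arrays. That between 6 h and 12 h was 28 without induced 6 h replicate 2, 22 and 24 without replicates 1 and 2 of the 12 h plants without induction, and 25 and 20 without induced 12 h replicates 1 and 2. That between 6 h and 24 h was 209 without induced 6 h replicate 3, 197 and 162 without replicates 2 and 3 of the 24 h plants without induction, and 623, 180 and 136 without induced 24 h replicates 1, 2 and 3.

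The change with time was measured in plants without induction, whose 6 h arrays also stood apart in their control probe sets. COR15A fell from 4460 ± 278 at 6 h to 988 ± 392 at 12 h and 542 ± 133 at 24 h (log2 change from 6 h to 24 h -3.06 ± 0.32 SE, adjusted p = 3.75e-06). AT3G02480, of the late embryogenesis abundant family, went from 459 ± 471 at 6 h to 17.56 ± 2.60 at 24 h (adjusted p = 9.85e-06), and LEA4-5 and COR47 fell by 2.66 and 0.86 over the same time. The iron deficiency response gene BHLH101 rose at least 3.96-fold between 6 h and 24 h, AT3G28550 at least 4.52-fold and AT3G61930 at least 2.63-fold, while AT4G37290 fell at least 3.88-fold. The light-harvesting gene LHCB4.2 fell by 0.90 (adjusted p = 0.000702), the zinc finger gene STZ by 1.12 (adjusted p = 0.00066) and the jasmonate methyltransferase gene JMT by 1.24 (adjusted p = 0.00708). RR16 rose by 1.32 and the Aurora genes AUR1 and AUR2 by 0.40 and 0.44.

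Between 6 h and 12 h, AT3G28550 rose at least 3.10-fold, and CML37 went from 8.63 ± 4.24, at background on 2 of 3 arrays, to background on all 3. Between 12 h and 24 h, AT1G07050 rose by 1.53, AT1G17665 by 1.51 and AT5G14330 by 1.44, AT1G13650 fell from 149 ± 36.5 to 32.7 ± 3.85 (adjusted p = 3.2e-06), the jasmonate-regulated gene JRG21 from 98.8 ± 31.3 to 23.9 ± 3.48, and AT5G20560 at least 2.55-fold. GI had log2 changes of 0.09, 0.41 and 0.50 over the 3 intervals (adjusted p = 0.831, 0.29 and 0.0516). The other largest changes by the naming rule were of genes near background. Of 3 detoxification genes, UGT73B4 fell between 6 h and 24 h (log2 change -0.79, adjusted p = 0.0274), and 2 passed adjusted over the list alone. Over that interval, 3 abscisic acid and drought genes, 3 photosynthesis genes, 2 touch and wound genes and 2 Aurora kinase genes passed adjusted over the list alone. So did JMT, RR16, GI and 1 egg cell gene, where for GI, the 1 measured clock gene, this was the unadjusted p.

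Without induction, 663 probe sets changed between 6 h and 12 h (328 up, 335 down), 329 between 12 h and 24 h (110 up, 219 down) and 2243 between 6 h and 24 h (1132 up, 1111 down). With each array shifted to 1 median the first and last became 213 up and 454 down, and 718 up and 1394 down. The first count was 434 without 6 h replicate 1, and 231 and 397 without 12 h replicates 1 and 2. The second was 208 and 155 without 12 h replicates 1 and 2, and 199, 200 and 169 without 24 h replicates 1, 2 and 3, and the last was 1475 without 24 h replicate 3. With the hybridisation controls as a covariate the counts between 6 h and 12 h and between 6 h and 24 h were 193 and 921. At 6 h, 12 h and 24 h these controls had mean log2 signals of 9.01, 8.49 and 8.29 in plants without induction. The 25S ribosomal RNA control had mean signals of 2518, 460 and 1176. Changes from 6 h could thus not be separated from these differences between arrays.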

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

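The tests of array noise, array quality, growing effects and drift with time below were chosen after the results they bear on had been seen, with predictions written before each was run.

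The effect of induction differed between times by limma's test of the difference itself. Between 6 h and 12 h this held for 44 probe sets. AT3G02480 (difference 3.31 on the log2 scale), AT2G41190 (2.79), AT2G37870 (2.19), AT4G33550 (1.82) and AT3G53980 (1.62) had a more positive effect at 12 h than at 6 h. AT2G37870 had signals of 114 ± 23.0 induced and 174 ± 21.9 not induced at 6 h, and 265 ± 58.3 and 91.9 ± 30.6 at 12 h. For AT3G02480 they were 159 ± 75.9 and 459 ± 471, then 179 ± 60.8 and 38.6 ± 7.42, and for AT2G41190 83.1 ± 21.4 and 160 ± 150, then 198 ± 41.4 and 42.8 ± 9.61. The 6 h changes of these 3 genes did not pass the test (adjusted p = 0.212, 0.312 and 0.57). AT5G10920 (-0.71), AT4G38710 (-0.81), the receptor-like kinase gene AT1G51830 (-1.31) and the peroxidase gene AT5G64120 (-1.49) had a more negative effect at 12 h. AT1G51830 and AT5G64120 fell at 12 h, by 1.77 and 2.31 on the log2 scale, while their 6 h changes of -0.46 and -0.82 did not pass (adjusted p = 0.293 and 0.0728). AT5G64120 stood at 130 against 230 at 6 h and 54.5 against 270 at 12 h. AT4G09410 (-7.62) was at background on 5 of 6 arrays at 6 h and 6 of 6 at 12 h. Neither the size nor the direction of its difference is thus known.

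Between 6 h and 24 h the effect differed for 367 probe sets. AT1G04645 (6.97), AT1G71470 (5.73), AT1G73510 (5.42), AT5G56770 (5.41) and AT4G00920 (5.30) had a more positive effect at 24 h, AT4G00920 with all arrays at background at both times, as was AT5G40645 below. AT1G71470 went from 4.75 induced against 2.79 not induced at 6 h to 25 against 4.42 at 12 h and 85.6 against 0.84 at 24 h. AT1G66440 (-4.76), AT3G28170 (-5.13), AT4G10210 (-5.15), AT4G15755 (-5.67) and AT5G40645 (-5.87) had a more negative effect at 24 h, each with at least 3 of 6 arrays at background at 24 h. Of these 5 genes only AT3G28170 passed at 6 h (adjusted p = 0.0444) and only AT1G66440 at 24 h (adjusted p = 0.00867). With signals raised to background the differences of AT3G28170, AT4G10210, AT4G15755 and AT5G40645 were positive (0.28, 0.37, 0.58 and 0.74). Signals at background then hold the level of their array, which was higher in induced plants at 24 h. The direction of these genes is thus not known. All 10 genes had arrays at background at both times, so their differences are not exact sizes. Of the 11 genes named for each of these pairs of times, 9 lost their call in some alternative. AT4G33550 and AT1G71470 kept theirs in every one that held their probe set.

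The splits of the arrays do not exclude chance for these counts. As many calls as the real 44 came from 7 of 100 drawn splits (highest other 1222), and as many as the real 367 from 10 of 100 (highest other 1637). Both shares count the real grouping. Between 12 h and 24 h the real count was 0, which all 100 splits reach whatever the data (highest other 810), so these splits tell nothing. A split that exchanges induced and not induced arrays at only 1 time adds the effects of both times, so these splits also measure the effect of induction.

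AT3G02480 and COR15A fell with time without induction and were higher in induced plants at 24 h, which may reflect a smaller drift with time in induced plants. The sum of 3 correlations between induction effects and time changes on other arrays was -0.37 (-0.02, -0.15 and -0.19). A sum as low came from 6 of 100 splits, the lowest other being -0.47, so this could not be told from chance. Opposite signs of effect were found at 24 h for 440 (66.4%) of the 663 probe sets changed between 6 h and 12 h without induction, at 12 h for 1275 (56.8%) of the 2243 changed between 6 h and 24 h, and at 6 h for 155 (47.1%) of the 329 changed between 12 h and 24 h.

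Fewer genes were called at 6 h (220) than at 12 h (1102) and 24 h (1894), although MGH3 and TET11 were called at each. The 6 h groups had the highest median SD of log2 signal over brighter probe sets, 0.163 without and 0.155 with induction. Later groups had 0.123 to 0.141. Noisier 6 h arrays alone would leave effects as large as later ones. Over probe sets called at 12 h, the slope of the 6 h on the 12 h change was 0.50 of that of the 24 h change (0.432 against 0.869, range of the ratio without 1 array 0.472 to 0.511), which argues against it. As to array quality, the 12 h count stayed 4.54 times the 6 h count without induced 6 h replicate 1. It was 9.04 times with the hybridisation controls as a covariate, where the 6 h count fell to 133. The fit without replicate 1 cannot decide, since its controls lay nearest those of the 6 h arrays without induction. Array quality was thus not excluded. Effects still growing after 6 h is an explanation that the medians allow: over the 24 h calls, the 12 h median change exceeded that of 6 h by 0.27 (0.20 to 0.33 without 1 array).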

How the results depend on the processing

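Of the alternatives, those adding background and covariate tests were chosen after the data were seen, and the others before the data were examined. Of 130 named results, the filter on mean signal held only 36 and so did not test the others. In the alternatives that held their probe set, 60 of the 130 kept direction and side of the threshold throughout. That count was 24 of 28 at 24 h, 17 of 25 at 12 h and 5 of 21 at 6 h. For differences of response it was 2 of 11 (6 h and 12 h), 1 of 1 (12 h and 24 h) and 2 of 11 (6 h and 24 h). Without induction it was 1 of 11 (6 h to 12 h), 3 of 11 (12 h to 24 h) and 5 of 11 (6 h to 24 h). Of the 130, 67 lost their call somewhere. Results that did not pass limma and stayed so count as kept, such as TET12 at 6 h and 12 h. The 1 of 1 was GI, which did not pass (limma, adjusted p = 0.92), so no stable difference between 12 h and 24 h is shown. GI was also 1 of the 2 kept for each other pair of times, and 1 of the 3 kept from 12 h to 24 h without induction. MGH3, COR15A and GSTU25 kept their calls at 24 h. Of the alternative values, 185 stayed close and 59 did not. The 185 include counts of lists passing camera, which stayed at 0 in each fit without 1 array and tell nothing about the gene counts. Close means counts within 1.5 times of the reported value, or 0 where it was 0, and correlations within 1 SD over left-out arrays. Quantile normalization, 1 median and leaving out probe sets of several genes moved no total count or correlation past these limits, although 1 median made falls outnumber rises at 6 h, 12 h and 24 h. For the others the cause was not tested, except where fewer arrays or probe sets were fitted. With array weights, 2974 changed at 24 h, 793 between 12 h and 24 h without induction, and 101, 12 and 583 differed in response between 6 h and 12 h, 12 h and 24 h, and 6 h and 24 h. With the filter, 82 and 2 differed for the first and second pair, and correlations of responses were 0.437 (6 h and 12 h), 0.396 (6 h and 24 h) and 0.740 (12 h and 24 h). With the offset, 68 differed between 6 h and 12 h, and the correlations were 0.338, 0.318 and 0.616. Without the trend, 6 and 88 differed between 6 h and 12 h and between 6 h and 24 h, and 239 and 126 changed without induction between 6 h and 12 h and between 12 h and 24 h. With the replicate block, 139 changed at 6 h, and 9 and 172 differed between 6 h and 12 h and between 6 h and 24 h. Only the arrays compared gave 67 at 6 h and 222 between 6 h and 12 h without induction. The covariate gave 133 at 6 h, 92 for the difference between 6 h and 24 h, and 193 and 921 for 6 h to 12 h and 6 h to 24 h without induction. Raising signals to background, 147 differed between 6 h and 12 h and 8 between 12 h and 24 h. This also reversed genes near background, as its construction implies: at 6 h AT3G54310 (-0.0114), AT3G12000 (-0.0696), AT4G09410 (-0.112) and AT2G04600 (-0.0504); TET12 at 24 h (0.0324); the differences of AT4G09410 (0.10), AT3G28170 (0.28), AT4G10210 (0.37), AT4G15755 (0.58) and AT5G40645 (0.74); without induction, AT1G54926 (-0.17), AT4G09410 (-0.19), AT3G12000 (-0.0453) and AT4G03880 (-0.10) between 6 h and 12 h, and AT1G54926 (-0.35) and AT5G40645 (-0.54) between 6 h and 24 h. Leaving out each array in turn gave 98 to 262 calls at 6 h, 615 to 915 at 12 h and 1161 to 2023 at 24 h, and 1828 to 2669 at any time. Differences between 6 h and 12 h ran from 20 to 65, between 12 h and 24 h from 0 to 18 and between 6 h and 24 h from 136 to 623. Without induction the ranges were 231 to 572 (6 h to 12 h), 155 to 302 (12 h to 24 h) and 1475 to 1932 (6 h to 24 h). The change of GI between 6 h and 12 h without induction ranged from -0.0672 to 0.246, with -0.0438 without 12 h replicate 1, and that of TET12 at 24 h from -2.03 to 0.0389. Background limits the fold changes of genes such as MGH3 and TET11 to lower bounds where all 3 arrays without induction lay at it. Where 2 of 3 did, only signals are given. Pairing by replicate number was not given in the labels, and deviations of same-numbered arrays correlated with r from -0.133 to 0.0969 within times and from -0.128 to 0.196 between times without induction. Alternatives for the DUO1 transcript were not run, as no probe set bore its name, and the block within each time, confounded with time, was replaced by the block across times for changes without induction.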

Other observations

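The tests of gene families and root genes below were chosen after the falls of EXPA7 and EXPA18 and the small number of measured list genes had been seen.

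Of 8 autophagy genes, 0 rose at 6 h, 2 at 12 h and 4 at 24 h after induction of DUO1. ATG8H stood at 186 ± 10.4 (SD, n = 3) against 59.5 ± 8.72 at 12 h (log2 change 1.66, adjusted p = 3.24e-05) and was higher by 1.5 at 24 h (adjusted p = 6.55e-05). ATG8G rose by 0.78 at 12 h, and ATG8B, ATG8C and ATG8D by 0.76, 0.52 and 0.59 at 24 h, whereas ATG8E and ATG8F had log2 changes of -0.52 and -0.05 at 24 h (adjusted p = 0.293 and 0.927). Among 48 gene families the 8 ATG genes passed camera at 12 h and 24 h (adjusted p = 0.00292 and 0.018), but the adjusted p was 0.643 and 0.537 with an estimated correlation. The 10 EXPA genes passed at 24 h, downward (adjusted p = 0.018, or adjusted p = 0.362 with an estimated correlation), with falls of EXPA7, EXPA18, EXPA8, EXPA9 and EXPA15. EXPA8 went from 150 ± 51.7 to 46.0 ± 11.0. With the filter on mean signal both families had an adjusted p of 0.104 at 24 h.

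Some tetraspanin genes other than TET11 also rose. TET10 rose at each time, by 0.63, 0.75 and 0.84 on the log2 scale, TET16 at 12 h and 24 h, TET4 at 12 h and TET14 at 24 h, while TET8 fell by 0.57 at 6 h (adjusted p = 0.0135). As a family, the 15 tetraspanin genes, TET11 included, did not pass camera at 12 h or 24 h (adjusted p = 0.157 and 0.146, or 0.643 and 0.533 with an estimated correlation). They passed fry (adjusted p = 0.0227 and 0.00502) and, with 4 rises at each time, Fisher's test of rises (adjusted p = 0.0309 and 0.0499), all with TET11 counted. With the filter on mean signal 7 of them were left, of which 1 rose at 12 h and 1 at 24 h (camera adjusted p = 0.456 and 0.737), and with the offset 3 of 15 rose at 24 h. Among genes that rose at all 3 times, the cytochrome P450 gene CYP78A9 had log2 changes of 1.87, 2.93 and 2.09 and the beta-galactosidase gene BGAL16 of 1.01, 2.22 and 1.71. The glutathione transferase gene GSTU22 fell by 0.58, 1.35 and 1.94 and GH3.17 by 0.64, 0.81 and 0.90.

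The falls of EXPA7 and EXPA18 could come from a lower share of root in the induced samples. The median 24 h change of 15 root genes other than root hair genes was -1.03 (-1.27 to -0.91 without 1 array). Of them 12 fell and 0 rose, so a lower root share and lower expression cannot be told apart. At 6 h and 12 h their median changes were smaller, -0.37 and -0.74, with 4 and 9 falls. The means of EXPA7 and EXPA18 were -1.195, -1.346 and -1.804 at 6 h, 12 h and 24 h. By a prediction written after these changes had been seen, a lower share as the whole cause would move every root gene alike, but 7 of 15 lay over 3 SE from their weighted mean of -0.98. AT4G30170 fell from 248 to 55.6 and PYK10 went from 3914 to 3258. This argues against a lower share as the whole cause only if these genes are expressed in root alone and their signals follow transcript level. Neither condition was tested. Lower expression of root hair genes is in line with the median change of -1.83 (-1.97 to -1.60) of 7 other root hair genes, of which 6 fell, among them GH9C1 (15.4 against 54.2) and AT1G30870 (46.5 against 184).

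For comparisons of 6 arrays, the 10 splits are too few for a share under 0.05. The real grouping was the 1 of 10 with the most calls at 6 h (220, highest other 11), 12 h (1102, highest other 0) and 24 h (1894, highest other 0), and between 6 h and 12 h (663, highest other 5), 12 h and 24 h (329, highest other 1) and 6 h and 24 h (2243, highest other 0) without induction. For whole lists at each time (highest other 1, 1 and 0) and for families at 6 h (highest other 4) the real count was 0, which all 10 splits reach whatever the data, so these splits tell nothing. For families 3 of 10 splits reached the real count at 12 h (1, highest other 2) and 3 of 10 at 24 h (2, highest other 2), so chance is not excluded. Over all times, 1 of 100 splits, the real one, gave 2377 calls (highest other 606). The correlations of responses were likewise reached by 1 of 100 splits: 0.175 for 6 h and 12 h (highest other 0.099), 0.183 for 6 h and 24 h (0.113) and 0.360 for 12 h and 24 h (0.191), so these values are unlikely to come from an arbitrary grouping of the arrays.

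Control probe sets differed between arrays. At 6 h the 25S ribosomal RNA control had signals of 2013, 550 and 233 in induced replicates 1, 2 and 3, and of 2891, 2036 and 2626 in plants without induction. The hybridisation controls had mean log2 signals of 9.23, 8.41 and 8.24, and of 9.10, 9.06 and 8.86. The background level was 10.1 in induced 6 h replicate 1 and 3.3 in replicate 3. At 24 h the background level was 5.93, 7.05 and 6.37 in induced replicates 1, 2 and 3, and 4.1, 4.60 and 4.45 in plants without induction, so the groups were fully separated. The hybridisation controls at 24 h were 8.25, 9.20 and 8.97 against 8.52, 8.34 and 8.01.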
